A study of Homo sapiens with 4 samples.

How the data were processed

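RNA was sequenced from 4 libraries of A375 cells, 2 of the parental line with wild-type p53 and 2 of a p53 knockout made with CRISPR-Cas9. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, enriched for polyadenylated RNA and turned into strand-specific libraries with an NEBNext Ultra II Directional kit. Groups were taken from the labels. The parental columns of the deposited table carry the labels' replicate numbers, while the knockout columns carry the numbers 2 and 8, which do not tell the labelled replicates apart; they were used as members of the knockout group and are named by those numbers.

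The deposited table holds, for 26484 gene symbols, a normalized signal per library: gene read counts that the authors had divided by 1 factor per library, as the values themselves show. Per the submitters' processing notes, STAR, Picard, HTSeq, DESeq2 and deepTools were used with build hg38; versions, the annotation, the order of steps, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Each value was a whole multiple of its library's step within 0.001 (100% of values in each library), which gave back whole reads, and the reciprocals of the steps (0.912, 1.14, 0.950 and 1.02 for parental 1, parental 2, knockout 2 and knockout 8) equalled median-of-ratios size factors computed from those reads. Such factors assume that most genes do not change, and they leave gene length uncorrected, so values compare libraries within a gene and not genes with each other. Genes with near-identical copies, and genes overlapping on opposite strands, are uncertain, because the counting settings are not known. The table has 0 mitochondrial and 0 repeat rows, so neither mitochondrial RNA nor LINE1 was measured here.

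Recovered reads totalled 29230554, 36331894, 30334054 and 32160978, in the same order. A group with 0 reads for a gene was given a floor of 3 reads over its libraries, or a mean normalized count of 1.52 in the knockout group; floors cover counting error only, since reads without molecular identifiers are not independent molecules. The parental pair and the knockout pair both differed beyond sampling noise (chi-square per degree of freedom 5.85 and 65.3), so no library was a copy of another.

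The design fixed before the data were examined named edgeR's quasi-likelihood test for raw counts and limma for normalized values. Since the table is normalized, the main test was limma 3.58.1 with a trend on log2(normalized count + 1), over 15431 genes with a normalized count of at least 10 in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and understate changes of weakly expressed genes. The edgeR 4.0.16 quasi-likelihood test (TMM, upper quartile and RLE factors), DESeq2 1.42.0 and limma-voom were run on the recovered reads as alternatives, DESeq2 over all 26484 rows with its own filter (16330 with an adjusted p) and the others over the 15431 genes; other alternatives were no low-count filter, at least 1 CPM in 2 libraries, a test against a 1.5-fold change, a pseudocount of 0.1, and leaving out each library in turn. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p below 33.3%, so none was used. Without a library, its group has 1 member, which is then assumed to vary like the other group.

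Gene lists (22 lists, 695 entries, of which 679 were found in the table, 47 through older symbols in RefSeq) were written before the data were examined. The 20 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 on the values of the main test, two-sided, with adjustment over the 20; the design had named voom values, which were run as an alternative. The mitochondrial list had 0 members in the table, and blood cell markers had 3 measured members. Estimated correlations, and fry, which tests whether a list's genes move on balance in one direction without comparing them with other genes, were alternatives.

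The rule for named genes, also fixed beforehand, was a few genes fixed by name, among them CDKN1A and MDM2, whatever their result; the 10 largest positive and negative log2 fold changes among called genes with a mean of at least 1 whose groups did not overlap; and up to 4 called members per list with the smallest adjusted p. As limma called 0 genes, the rule was applied to the DESeq2 calls, a choice made after seeing the data. Results for some genes that the rule names, and for 1 chromosome segment, are not reported here. Other list members, and genes in the closing section, were named after their values were seen.

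Gene positions were taken from GENCODE 29 on GRCh38 for the 23824 symbols with 1 locus. Median log2 ratios of 40 neighbouring genes with a mean of at least 100, in steps of 10 genes, were compared with the 95th percentile of the largest medians over 1000 permutations of gene positions; windows and thresholds were chosen after seeing the data. Leaving out the genes of such segments, DESeq2 without each library, DESeq2 over the 15431 genes of the main test alone, and camera on voom values with TMM factors were added after seeing the data, as was edgeR with TMM.

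The tests were tried on simulated data: reads for the same 15431 genes with 100 genes changed 2-fold and 100 changed 4-fold, over 5 draws. With the read spread rescaled so that the median residual SD (0.140 to 0.143) was close to that of the data (0.141), limma recovered 27 to 42 of the 2-fold and 72 to 80 of the 4-fold changes per draw, with 6 to 14 calls on unchanged genes. DESeq2 recovered 77 to 84 and 94 to 97, with 125 to 169 calls on unchanged genes. On the data limma called 0 genes, so its recovery rates in these draws need not hold for the data. The rescaling was introduced after simulations with each group's own dispersion trend came out wider than the data (residual SD 0.196 to 0.202); there limma recovered 0 of the 2-fold and 22 to 32 of the 4-fold changes, and DESeq2 called 235 to 275 unchanged genes. For camera, 20 lists of 30 genes picked at random were used, with 1 list shifted by 0.4 on the log2 scale. At the preset correlation camera called the shifted list and 0 of the other 19 in each draw. The simulated genes varied independently. These draws therefore do not show how often camera miscalls lists of genes that vary together, nor whether it finds smaller shifts or shorter lists. Analyses used R 4.3.3, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.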

Results

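Gene expression was measured by poly(A)-selected RNA sequencing in A375, a human melanoma cell line, and in a derivative of it in which the tumour suppressor p53 had been knocked out with CRISPR-Cas9. There were 4 libraries, 2 from the parental line and 2 from the knockout. The deposited normalized counts gave back whole reads, with totals of 29230554 and 36331894 in parental libraries 1 and 2, and 30334054 and 32160978 in knockout libraries 2 and 8 (numbered as in the deposited table). The labels do not say whether the libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries. The series title concerns repression of LINE1 transposons by p53; the table used here has 0 rows for repeat elements, and LINE1 expression was not analysed here.

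The comparison asks how the transcriptome of A375 cells differs once p53, a transcription factor, is lost. No edited cells that kept p53 were among the libraries. Effects of p53 loss therefore cannot be told apart from those of editing or of selecting the edited cells. Several direct p53 targets, led by EDA2R, GDF15, BTG2 and DDB2, were lower in both knockout libraries, whereas CDKN1A and MDM2, among the best known p53 targets, were not called. By camera with a preset correlation, genes of cholesterol synthesis were lower as a list and genes of NF-kB-driven inflammation, 9 of whose 29 measured members DESeq2 called, were higher. Neither list was called with its correlation estimated (adjusted p = 0.512 with an estimated correlation for both) or by fry (adjusted p = 0.223 for both). An estimated correlation rests here on 2 residual degrees of freedom, and no list tested had a smaller adjusted p under it. That setting was not tried on the simulated data, and a call lost under it does not show that a list is unchanged. The preset correlation was tried only on simulated genes that varied independently. How often it miscalls lists of genes that vary together is therefore not known. The knockout libraries also differed from each other far more than the parental ones did, including over whole chromosome segments.

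Over all 15431 genes tested, limma called 0 genes at an adjusted p of 0.05 (smallest adjusted p 0.121), with 903 genes higher and 950 lower at an unadjusted p under 0.05. The edgeR quasi-likelihood test on the recovered reads also called 0 (946 higher and 921 lower at an unadjusted p under 0.05), as did limma-voom (873 and 957). DESeq2, run on the reads of all 26484 rows, 16330 of which received an adjusted p, called 198 genes higher and 200 lower. Run on the 15431 genes alone it called 199 and 200, and 394 calls were shared. In each of these 398 genes both knockout libraries lay beyond both parental ones, as they did in 46.4% of the 15431 genes. Chance gives 33.3% if all 4 libraries vary alike, and unchanged genes simulated with each group's own spread gave 38.1% to 38.9% per draw when rescaled to the median residual SD of these libraries and 39.5% to 40.3% without rescaling. The gap to 46.4% was not tested, since genes are not independent. In the rescaled simulation, over the same 15431 genes, DESeq2 called 125 to 169 unchanged genes per draw, against 6 to 14 for limma. Without rescaling, which came out wider than the data, DESeq2 called 235 to 275, so a large part of its calls can be false. Without parental library 1, DESeq2 still called 36 of the 398 genes, and without parental library 2 it called 44 of them, against 348 without knockout library 2 and 387 without knockout library 8. Single genes given as called, higher or lower rest on DESeq2 unless another test is named, and none of them was called by limma, edgeR or limma-voom when adjusted over all genes tested. One of them, LRRC55, fell below the count filter of those 3 tests. Adjusted over the list alone, limma called members of 9 lists, given with each list, and 0 members of the other 11 lists tested.

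Among 92 genes that p53 is known to activate, DESeq2 called 11 lower and 5 higher (13 and 6 when adjusted over the list alone); limma over the list alone called 13 lower and 3 higher. The lower ones included EDA2R, a receptor of the tumour necrosis factor family, at 252 and 250 normalized counts in the parental libraries against 16.8 and 42.0 in knockout libraries 2 and 8 (adjusted p = 3.46e-08). DDB2, a DNA damage recognition protein, had 2094 and 2126 against 1019 and 1138 (adjusted p = 3.46e-08). BTG2, an antiproliferative gene, had 587 and 527 against 190 and 282 (adjusted p = 9.76e-04). GDF15, TP53INP1, SESN1, ZMAT3, RPS27L, AEN, ZNF337 and CCNG1 completed the 11. The 5 higher members were PRDM1, LAPTM5, FAS, PMAIP1 and LIF, and PRDM1 went from 49.3 and 35.1 to 429 and 220 (adjusted p = 3.46e-08). EDA2R and GDF15 lie in segments that were lower as a whole in knockout library 2, and BTG2 in one that was lower in knockout library 8.

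CDKN1A, the cyclin-dependent kinase inhibitor p21, had 3561 and 3889 normalized counts in the parental libraries, against 4898 in knockout library 2 and 2603 in knockout library 8. The knockout libraries thus lay on either side of the parental ones, and the log2 fold change was -0.06 ± 0.31 by limma (adjusted p = 0.951) and 0.0095 ± 0.29 by DESeq2 (adjusted p = 0.998). Leaving out a knockout library gave CDKN1A opposite calls by limma, a log2 fold change of -0.52 without library 2 (adjusted p = 2.79e-04) and of 0.40 without library 8 (adjusted p = 0.00155). MDM2, the ubiquitin ligase that degrades p53, had 4359 and 4775 against 4325 and 4111 (limma log2 fold change -0.11 ± 0.09, adjusted p = 0.639). As a list, the p53-activated genes were lower by camera, with a median log2 fold change of -0.08 (adjusted p = 0.0384). That call was lost with an estimated correlation (adjusted p = 0.512 with an estimated correlation), without parental library 2 (0.0715), without knockout library 2 (0.105), without knockout library 8 (0.0911), and when genes in shifted segments were left out (0.124).

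**Figure D1:**
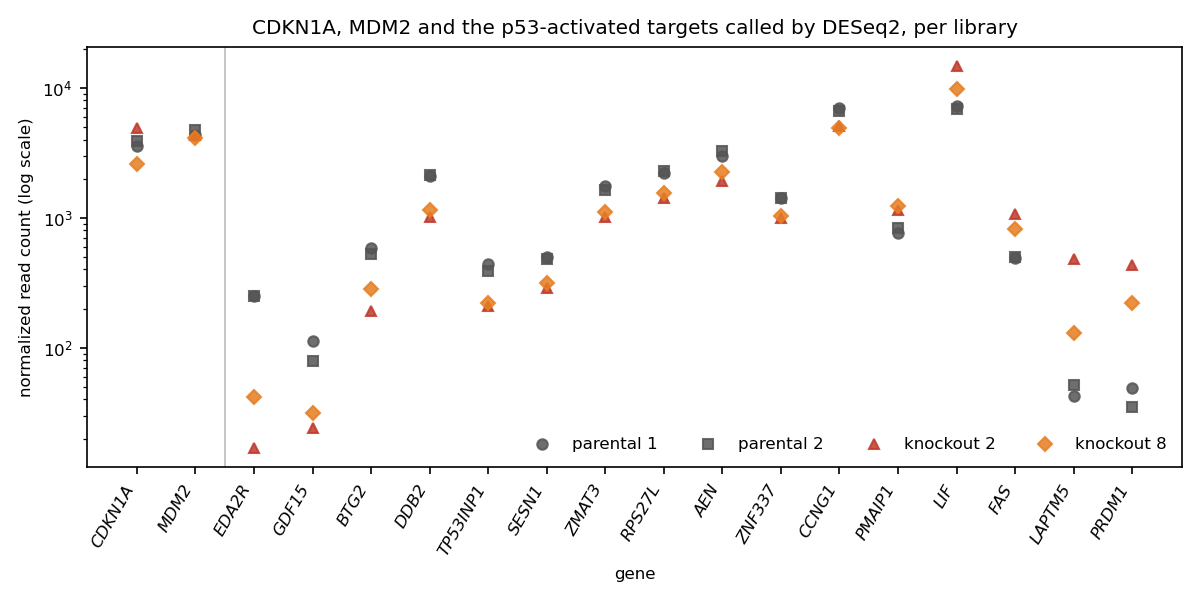
Normalized read counts on a log scale of CDKN1A and MDM2 (left of the line) and of the 16 p53-activated genes called by DESeq2, ordered by fold change; each point is 1 library. EDA2R has 252 and 250 in the parental libraries and 16.8 and 42.0 in the knockout libraries, and CDKN1A has its knockout libraries on both sides of the parental ones.

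Genes of cholesterol synthesis and uptake gave the smallest list p by camera with the preset correlation. Of 23 measured members, 19 were lower in both knockout libraries than in either parental library and 0 were higher in both; 11 were called lower and 0 higher by DESeq2 (17 and 0 adjusted over the list alone, and 17 by limma over the list alone). INSIG1, a sterol-sensing regulator, went from 5753 and 5928 to 2424 and 3265 (adjusted p = 8.53e-06). HMGCS1, an early enzyme of the mevalonate pathway, went from 5669 and 6579 to 3213 and 3663 (adjusted p = 2.41e-05). FDFT1, squalene synthase, went from 7925 and 7932 to 5246 and 5230 (adjusted p = 2.50e-05). Of the measured members, 4 lie in segments that were shifted in 1 knockout library. The list's median log2 fold change was -0.49 by limma (camera adjusted p = 1.88e-13). By camera the list was called without each library in turn, but not with its own correlation estimated (adjusted p = 0.512 with an estimated correlation).

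Inflammatory genes driven by NF-kB were higher as a list, with a median log2 fold change of 0.41 over 29 measured members (camera adjusted p = 1.27e-05; adjusted p = 0.512 with an estimated correlation). Of the measured members, 16 were higher and 3 lower in both knockout libraries than in either parental library, and 4 lie in shifted segments. Between the parental libraries, library 2 minus library 1, the median of the list was -0.15. DESeq2 called 9 members higher and 0 lower (14 and 0 adjusted over the list alone, and 9 and 0 by limma over the list alone). The chemokine CCL2 went from 667 and 690 normalized counts to 1557 and 2230 (adjusted p = 2.82e-08), and CXCL8, interleukin 8, from 12830 and 11149 to 29465 and 21814 (adjusted p = 3.63e-06). TNFAIP3 and NFKBIA, inhibitors that NF-kB itself induces, went from 884 and 876 to 1949 and 1636 (adjusted p = 5.84e-07) and from 2398 and 2147 to 3336 and 3192 (adjusted p = 0.0122). The other called members were IL1B, LIF, NFKB1, NFKB2 and RELB. Other members parted between the knockout libraries: CCL20 had 217 and 166 in the parental libraries, 47.4 in knockout library 2 and 526 in knockout library 8.

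Interferon-stimulated genes were higher by camera (adjusted p = 0.0125; adjusted p = 0.512 with an estimated correlation), mostly in knockout library 2, where the median log2 ratio to the parental mean was 0.53, against 0.15 in knockout library 8. The list call was lost without knockout library 2 (adjusted p = 0.151). Of 47 measured members DESeq2 called 3 higher and 1 lower (9 and 3 adjusted over the list alone, and 1 and 0 by limma over the list alone). Among the higher ones were IFI44L, at 14.3 and 12.3 against 215 and 32.2 (adjusted p = 0.0174), and SAMD9, at 1001 and 960 against 1766 and 1377 (adjusted p = 0.0219). Of the measured members, 4 lie in segments that were shifted in 1 knockout library. The exonuclease gene ISG20 was lower, from 3288 and 3629 to 1929 and 2281 (adjusted p = 9.63e-04).

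Genes that sense nucleic acids were not called as a list (camera adjusted p = 0.433), and 2 members were lower: AIM2, a sensor of cytosolic DNA, from 1639 and 1557 to 718 and 1017 (adjusted p = 0.00552), and IFI16, from 5592 and 5254 to 4197 and 4005 (adjusted p = 0.0499). Both lie in a part of chromosome 1 that was lower in knockout library 8. Genes that restrict retroelements, including the APOBEC3 family, the HUSH complex, DNA methyltransferases and TRIM28, were not called as a list (camera adjusted p = 0.573), and DESeq2 called 0 of its members, with 6 of 38 at an unadjusted limma p under 0.05. The median of that list was 0.0051 and its mean -0.04, and the test pointed down. Antigen presentation genes were not called either (adjusted p = 0.677), although TAPBP, tapasin, was higher, from 2947 and 2905 to 4210 and 3875 (adjusted p = 0.0179). Of 25 measured members, 7 were higher and 9 lower in both knockout libraries than in either parental library. The median log2 ratio of this list to the parental mean was -0.30 in knockout library 2 and 0.05 in knockout library 8.

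Markers of the undifferentiated melanoma state and genes of extracellular matrix and mesenchymal character were higher by camera (adjusted p = 0.0384 and 0.0448; adjusted p = 0.810 with an estimated correlation for both), and both calls were lost without knockout library 2 (0.581 and 0.697). In knockout library 8 the medians of both lists lay below 0 (-0.08 and -0.02), against 0.40 and 0.30 in knockout library 2. Without genes in shifted segments both calls were lost as well (0.0939 and 0.176), and that of the second list was also lost without parental library 2 (0.0715), under the stricter filter (0.120) and on voom values (0.0565 with RLE and 0.0514 with TMM factors). In the first list 5 of 30 members were called higher and 1 lower (7 and 1 adjusted over the list alone, and 1 and 1 by limma over the list alone). JUN, an AP-1 subunit, went from 421 and 474 to 1008 and 1601 (adjusted p = 3.60e-06), and TGFBI from 7690 and 7101 to 9944 and 12379 (adjusted p = 0.0168). CYR61, a matricellular protein, went the other way, from 1521 and 1706 to 769 and 753 (adjusted p = 6.73e-09). In the second list 4 of 36 were called higher and 1 lower (10 and 3 adjusted over the list alone, and 4 and 0 by limma over the list alone). VCAN, the proteoglycan versican, went from 298 and 255 to 1417 and 929 (adjusted p = 2.02e-11), while VIM, vimentin, went from 75622 and 69314 to 52686 and 42757 (adjusted p = 0.00987). ITGAV and COL6A3, also higher, lie in the chromosome 2 segment that was higher in knockout library 8.

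Fibroblast markers, included as markers of another cell type, were higher by camera over 7 measured genes (adjusted p = 0.0448; adjusted p = 0.512 with an estimated correlation), a call lost without parental library 2 (0.0715) or knockout library 2 (0.274). Abundant fibroblast transcripts stayed near 0: COL1A2 had 1.10, 3.51, 1.05 and 0.977 normalized counts and COL3A1 had 1.10, 0.877, 0 and 0, in the order parental 1, parental 2, knockout 2 and knockout 8. Epithelial markers were not called (adjusted p = 0.719), and only 3 of 15 blood cell markers were measured, too few to test. Pigmentation genes were not called as a list (adjusted p = 0.691; median -0.06, mean 0.07), while MITF, the melanocyte master regulator, was lower, from 1645 and 1562 to 849 and 1050 (adjusted p = 0.00272). Adjusted over the list alone, DESeq2 called 1 pigmentation gene higher and 1 lower, and limma 2 and 1.

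Immediate early genes (adjusted p = 0.390) and transcriptional outputs of MAPK signalling (adjusted p = 0.682) were not called as lists. Each held called members, and limma adjusted over the list alone called 3 immediate early genes higher. The transcription factors EGR2 and NR4A1 were higher, EGR2 from 195 and 147 to 1056 and 1253 (adjusted p = 3.87e-28) and NR4A1 from 5480 and 6947 to 10285 and 9234 (adjusted p = 0.0109). LIF and IER3 were higher, at 14686 and 9841 against 7211 and 6889 (adjusted p = 0.0139) and at 19085 and 13303 against 9939 and 10399 (adjusted p = 0.0432), and SPRY2, a feedback inhibitor of the pathway, was lower, at 8015 and 8575 against 10926 and 10853 (adjusted p = 0.0388).

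Cell cycle genes gave no call with all libraries, and their medians differed within both groups. The median log2 ratio of G2/M genes to the parental mean was 0.14 in knockout library 2 and -0.22 in knockout library 8 (camera adjusted p = 0.470), and the list was called lower without knockout library 2 (adjusted p = 1.20e-08) but higher without knockout library 8 (adjusted p = 0.00112). G1/S genes under E2F control had medians of 0.28 and -0.07 (adjusted p = 0.105). Between the parental libraries, library 2 minus library 1, the medians were 0.14 for G2/M and 0.17 for G1/S genes. DESeq2 called 0 members of either list, and limma gave 0 and 2 of 38 members each an unadjusted p under 0.05. Of 41 replication-dependent histone genes, 15 were measured in these poly(A)-selected libraries. As a list they were higher by camera (adjusted p = 0.0472, and 0.810 with an estimated correlation). That call was lost without knockout library 8, whose median was 0.60 against 0.05 in knockout library 2, or without parental library 2. It was also lost under the stricter filter (camera adjusted p = 0.161) and without genes in shifted segments (0.124). The median of this list differed by -0.39 between parental libraries 2 and 1, about as much as its knockout median of 0.41. Hypoxia and glycolysis genes (adjusted p = 0.0636), targets of ATF4 and the unfolded protein response (0.0964) and cancer-testis antigens (0.319) were not called; 1 cancer-testis gene was lower by limma adjusted over the list alone.

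**Figure D2:**
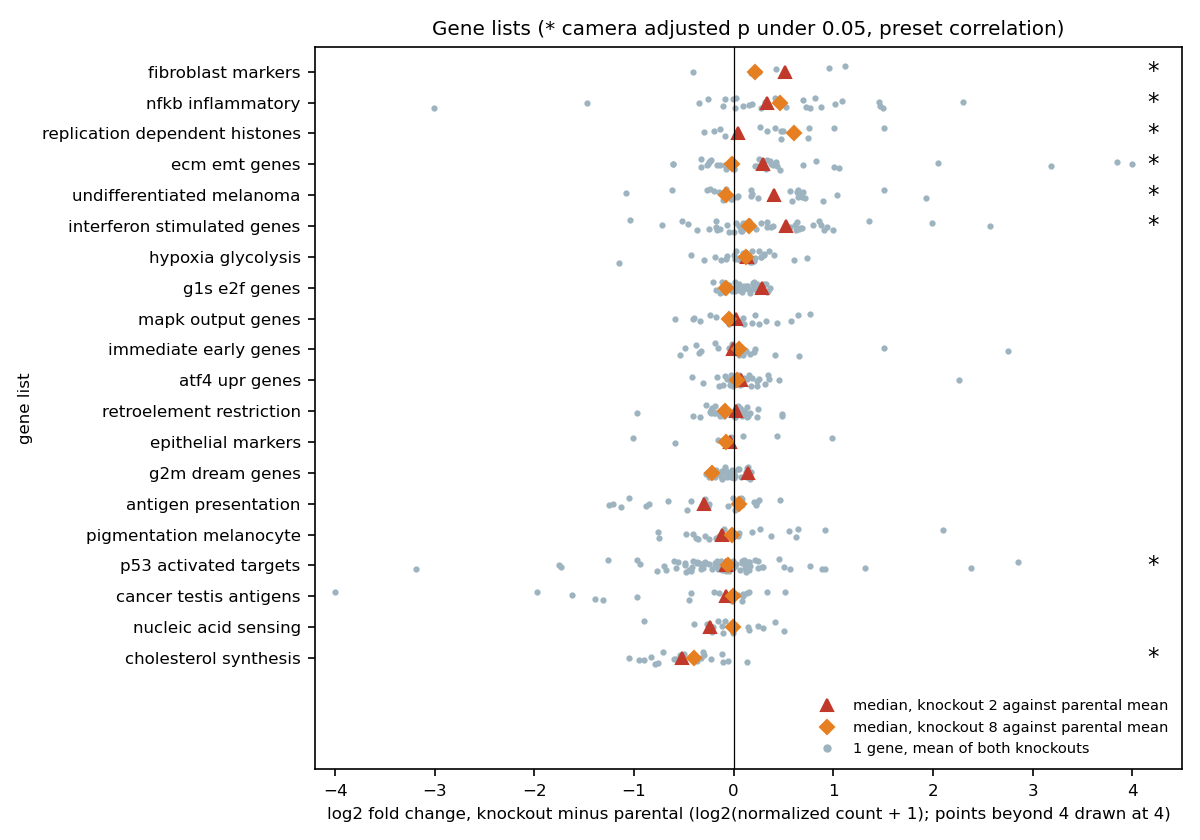
Log2 fold changes (knockout minus parental, log2 of normalized count + 1) of the members of the 20 gene lists tested, with 1 grey point per gene and the list median of each knockout library against the parental mean; stars mark camera adjusted p under 0.05 with a preset correlation. Cholesterol synthesis has both medians below 0 (-0.51 and -0.40) and the NF-kB list both above (0.34 and 0.46), whereas G2/M genes have medians of opposite sign (0.14 and -0.22).

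The largest falls called by DESeq2 were in genes of low expression. PRSS3, mesotrypsin, had 65.8 and 57.0 normalized counts in the parental libraries and 0 in both knockout libraries, at least 40.3-fold lower against a floor of 3 reads over the group (adjusted p = 3.18e-05), although it belongs to a family of near-identical trypsinogen genes whose reads could be split. RNF17 and FGL2 were likewise at 0 in both, at least 23.3-fold (adjusted p = 0.00101) and 12.4-fold lower (adjusted p = 0.0251). The cancer-testis genes GAGE1 and CT55 had 45.0 and 63.2 against 2.11 and 1.95 (adjusted p = 2.31e-04), and 35.1 and 38.6 against 2.11 and 0.977 (adjusted p = 0.00512). GAGE1 shares reads with near-identical copies and is uncertain. BANCR, a BRAF-activated long non-coding RNA, went from 91.0 and 80.7 to 5.26 and 8.79 (adjusted p = 7.09e-06). TSSC2, a transcribed pseudogene, LPAR4, ADRA2A and EDA2R completed the 10 largest.

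The largest rises called by DESeq2 were often larger in knockout library 2 than in knockout library 8, though both lay above both parental libraries. LRRC55 had 2.19 and 1.75 normalized counts in the parental libraries, 446 in knockout library 2 and 8.79 in knockout library 8 (adjusted p = 0.0463), and the matrix metalloproteinase gene MMP9 had 2.19 and 5.26 against 469 and 27.3 (adjusted p = 0.0274). DCLK1, GAP43, C6orf58, TIE1, IFI44L and LOC101927120 were also more than 2-fold apart between the knockout libraries. CHRNA3, a nicotinic receptor subunit, and SSTR2, a somatostatin receptor, were closer, at 24.2 and 26.4 against 0 and 1.75 (adjusted p = 0.0441) and at 41.0 and 22.5 against 0 and 2.63 (adjusted p = 0.0304).

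The knockout libraries differed from each other more than the parental libraries did. Over 12276 genes with a mean normalized count of at least 100, the SD of the log2 ratio was 0.50 between the knockout libraries and 0.14 between the parental ones, and 527 genes against 5 differed more than 2-fold. Part of this followed gene position. Median log2 ratios to the parental mean over 40 neighbouring genes went beyond the bound from permuted gene positions in 50 of 1110 windows in knockout library 2 and in 79 in knockout library 8, against 0 between the parental libraries. In knockout library 2 the genes of chromosome 19 from 0.3 to 21.9 Mb (390 genes) had a median of -0.48, those of chromosome 11 from 113.0 to 134.4 Mb (99 genes) one of 0.36, and those of chromosome X from 55.7 to 74.1 Mb (40 genes) one of -0.24. In knockout library 8 the genes of chromosome 2 from 159.2 to 241.8 Mb (282 genes) had a median of 0.46 and those of chromosome 1 from 168.2 to 222.7 Mb (190 genes) one of -0.25. Shifted segments held 13.4% of the genes tested and 61 (15.3%) of the 398 genes DESeq2 called.

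**Figure D3:**
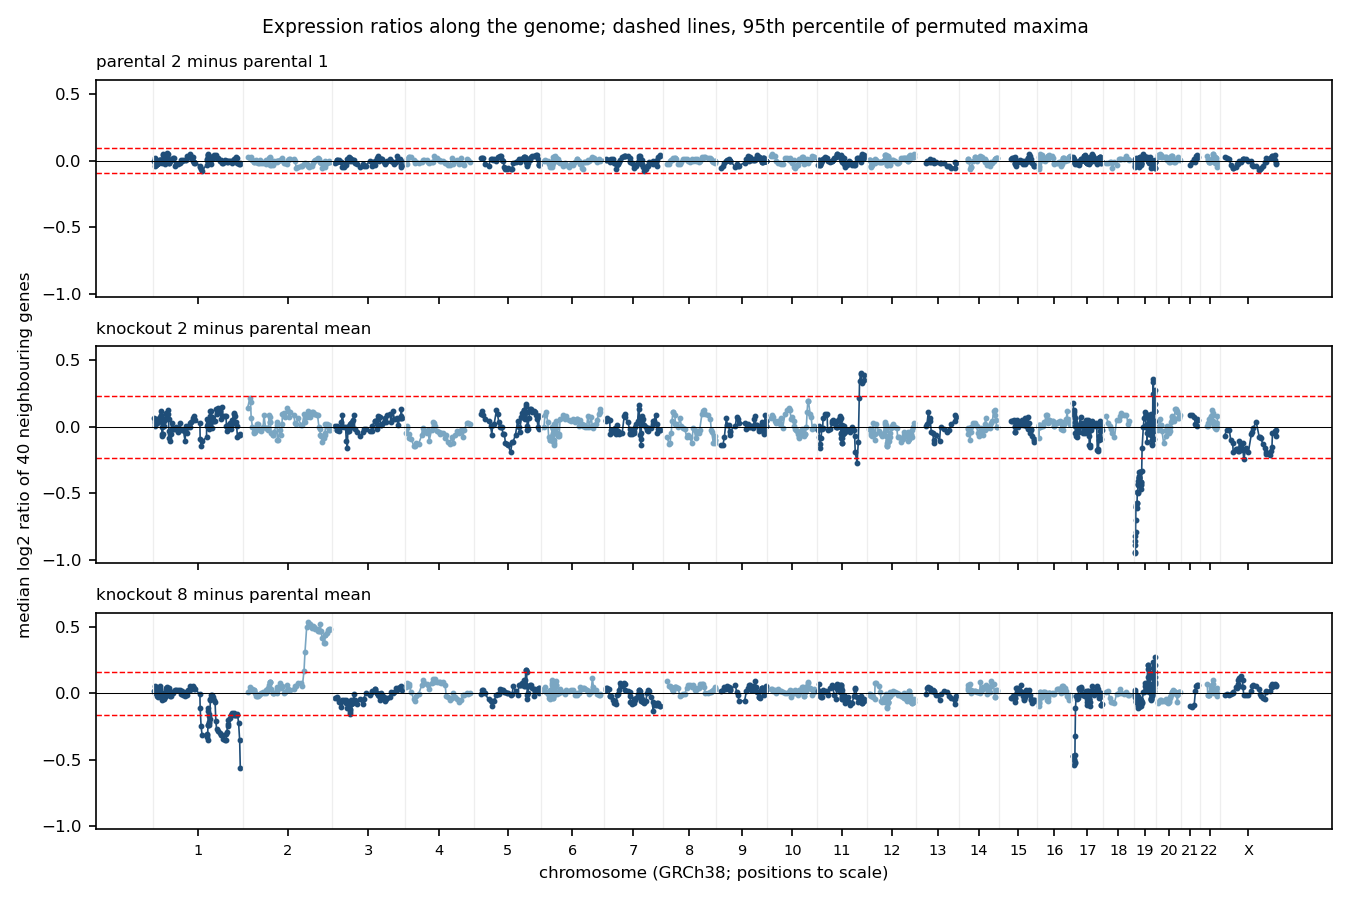
Median log2 ratio of 40 neighbouring genes along chromosomes 1 to 22 and X (GRCh38) for parental library 2 against 1 and for each knockout library against the parental mean; each point is 1 window and dashed lines mark the 95th percentile of the largest medians under permuted gene positions. The parental ratio has 0 windows beyond the lines, knockout library 2 reaches -0.95 on chromosome 19, and knockout library 8 reaches 0.53 on chromosome 2.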

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

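The DESeq2 runs without a library or over the genes of the main test alone, the runs without genes in shifted segments, voom with TMM factors and edgeR with TMM were chosen after seeing the data. No paired analysis was possible because the knockout columns carry the numbers 2 and 8, which could not be matched to the labels' replicate numbers 1 and 2. The count of limma calls, 0 in each direction, was also 0 with edgeR under 3 scalings, limma-voom, both other filters, the 1.5-fold test and the 0.1 pseudocount, with 903 higher and 950 lower at an unadjusted p under 0.05. DESeq2 called 198 higher and 200 lower, and 199 and 200 over the 15431 genes of the main test alone. Without single libraries limma gave 0 to 2421 higher (1309 without knockout library 2, 2421 without knockout library 8, 0 without either parental library) and 0 to 2602 lower (1587 and 2602 in the same order). Fits without a knockout library took their spread from the parental pair alone, which differs less than the knockout pair. DESeq2 gave 28 to 1215 higher and 11 to 1396 lower (28 and 11 without parental library 1, 30 and 16 without parental library 2, 521 and 749 without knockout library 2, 1215 and 1396 without knockout library 8). CDKN1A changed sign to 0.0095 with edgeR and TMM, 0.014 with RLE, 0.0154 with the upper quartile and 0.00953 with DESeq2, and ran from -0.52 to 0.40 without single libraries (0.40 without knockout library 8, 0.0038 without parental library 2).

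With an estimated correlation no list kept its call: adjusted p was 0.512 for p53-activated, interferon, NF-kB, cholesterol and fibroblast lists and 0.810 for the undifferentiated melanoma, matrix and histone lists. That setting rests on 2 residual degrees of freedom and was not tried on the simulated data. A call lost under it does not show that a list is unchanged. With fry the values were 0.126 for p53-activated genes, 0.223 for interferon, NF-kB, cholesterol and fibroblast lists and 0.568 for the undifferentiated, matrix and histone lists. The stricter filter gave 0.120 for the matrix and fibroblast lists and 0.161 for histones, and voom gave the matrix list 0.0565 with RLE and 0.0514 with TMM factors. Without genes in shifted segments the values were 0.124 for p53-activated genes, histones and fibroblast markers, 0.0939 for the undifferentiated list and 0.176 for the matrix list. Without single libraries, cholesterol and NF-kB lists kept their calls in each run. The ranges of adjusted p for lists that lost a call were 0.0134 to 0.105 for p53-activated genes (0.0715 without parental library 2, 0.0911 without knockout library 8), 7.88e-04 to 0.151 for interferon genes, 9.75e-06 to 0.581 for the undifferentiated list, 2.42e-05 to 0.697 for the matrix list (also 0.0715 without parental library 2), 0.00275 to 0.671 for histones and 0.0138 to 0.274 for fibroblast markers (0.0715 without parental library 2). For lists that gained one they were 1.20e-08 to 0.595 for G2/M (lower at 0.0138 without parental library 1 and at 1.20e-08 without knockout library 2, but reversed to higher at 0.00112 without knockout library 8), 1.99e-05 to 0.875 for G1/S (also 5.01e-04 without parental library 2), 6.89e-05 to 0.585 for antigen presentation, 0.0292 to 0.702 for cancer-testis genes and 1.53e-05 to 0.712 for hypoxia genes. Apart from the use of the parental spread, the cause was not tested. Depth limits weakly expressed genes, since 0 reads in both knockout libraries still allow a mean of 1.52 normalized counts.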

Other observations

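The tests of gene order and of the GC trend in zinc finger genes were chosen after the result was seen, and genes outside the naming rule were picked from their values. The genes with the smallest DESeq2 adjusted p were led by ACPP, an acid phosphatase, at 370 and 322 normalized counts in the parental libraries against 1705 and 1772 in knockout libraries 2 and 8 (adjusted p = 2.41e-38). STC1, a secreted glycoprotein hormone, went from 1220 and 1187 to 3978 and 4662 (adjusted p = 1.95e-29), and AREG, the epidermal growth factor receptor ligand amphiregulin, from 123 and 141 to 1342 and 947 (adjusted p = 7.56e-29). BOC, a hedgehog co-receptor, was lower, from 2105 and 1869 to 425 and 517 (adjusted p = 1.51e-25). ACSS2, which makes acetyl-CoA from acetate and was not on the cholesterol list, was lower too, from 8884 and 8262 to 3280 and 3729 (adjusted p = 6.35e-17), as was the abundant ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, from 65863 and 61317 to 27751 and 30507 (adjusted p = 7.73e-16). limma gave these 6 genes adjusted p of 0.121 to 0.169.

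Several genes differed more than 10-fold between the knockout libraries. PXDN, peroxidasin, had 946 and 829 normalized counts in the parental libraries, 6015 in knockout library 2 and 64.5 in knockout library 8, and CDCP1 had 3267 and 2988 against 4557 and 128. IL24 went the other way, with 6183 and 7465 in the parental libraries, 219 in knockout library 2 and 3225 in knockout library 8. By a rule of at least 20 normalized counts in one library and at most 3 reads in the other, 45 genes were on in knockout library 2 only and 30 in knockout library 8 only, against 1 and 0 between the parental libraries. By the same rule over groups, 3 genes were off in both knockout libraries (CT55, PRSS3 and RNF17) and 2 were on in both (CHRNA3 and SSTR2); the 6 nearest measured neighbours of the first 3 had a median log2 fold change of -0.10.

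Neighbouring genes shifted together in each knockout library. Chance placement was argued against by 50 windows beyond the permuted bound in knockout library 2 and 79 in knockout library 8, where 0 of 1000 permutations reached the largest observed median. A trend on GC content and gene length was argued against too, since after its removal the medians were -0.44 on chromosome 19 in knockout library 2, and 0.44 on chromosome 2 and -0.25 on chromosome 1 in knockout library 8. Gains and losses of chromosome segments in the knockout cells may account for these shifts; this remains a hypothesis, as DNA copy number was not analysed here, and no biological explanation was tested.

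The knockout libraries were further apart than the parental ones, with 527 against 5 genes over 2-fold apart. Sequencing depth was argued against, since after thinning to equal read totals the SD of log2 ratios was still 3.42 times that of the parental pair. The shifted segments were argued against as the main source by the SD of log2 ratios between the knockout libraries. It was 0.48 over the 10605 genes outside the segments, against 0.50 over all 12276 genes. Of the 527 genes, 78.0% lay outside the segments. That share says little by itself, since segment medians ran from -0.48 to 0.46, short of a 2-fold change. Knockout libraries 2 and 8 may come from separate clones, which the column numbers would allow and the labels do not state; this, and any effect of p53 loss on variation between cells, was not tested.

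Zinc finger genes near the end of chromosome 19 (49.9 to 58.3 Mb) were higher in both knockout libraries, with medians of 0.26 (64 of 77 genes above 0) in library 2 and 0.23 (67 of 77) in library 8, against -0.0356 between the parental libraries. The lowest share of the median left after removing a trend on GC content and gene length was 0.935. A copy number gain of the segment was argued against by its 63 other genes, with medians of -0.0505 and 0.0295, and a change of the whole class by zinc finger genes on other chromosomes, with medians of -0.0139 and 0.001. The 126 zinc finger genes elsewhere on chromosome 19 had a median of 0.0881 in library 8 (bootstrap interval 0.0151 to 0.138, 78 above 0). That set takes in the part from 35.7 to 38.9 Mb, which was higher as a whole in library 8 (60 genes, median 0.15). Whether the shift in library 8 was limited to the segment therefore cannot be told from this set. In library 2 the median of the 126 genes was -0.0351. The same set takes in the part from 0.3 to 21.9 Mb, which was lower as a whole in library 2 (median -0.48). Its median therefore cannot show whether the shift in library 2 was limited to the segment. A regulatory change after p53 loss and reads shared between these related genes stay open as untested, and the segment was chosen in the same data, against the same parental libraries for both knockout libraries.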
